A study of Homo sapiens with 16 samples.

How the data were processed

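Nuclei of human spinal cord from organ donors were profiled by STAB-seq, which combines antibody-directed tagmentation of 1 histone mark with tagmentation of accessible DNA in the same nucleus. The 16 libraries comprised 9 from the lumbar segment L4 and 7 from the thoracic segment T4. By mark, 7 libraries carried H3K27ac, 6 carried H3K4me1 and 3 carried H3K27me3. Each segment came from 1 donor, a different one for each segment, so segment and donor cannot be told apart, and p-values measure the spread between libraries of the same donors.

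The deposited values are counts per peak and nucleus, as whole numbers, in a pair of tables named DualCC and noCC that share 445837 peaks. The submitters' processing notes list MACS2 2.2.7.1, ArchR 1.0.3 and the build GRCh38, without their order or settings. Whether reads, fragments or insertions were counted, and how fragments were divided between the tables, is not given in the sources used here. The labels also do not say which table holds the antibody-directed fragments, so both tables received the same tests. The DualCC table was read as antibody-directed from its values: between H3K27ac and H3K27me3 libraries, Pearson's r across genes ran from 0.322 to 0.466 in DualCC and from 0.932 to 0.984 in noCC. Genes are not independent replicates in these correlations. All 42743 nuclei found in both tables were used, and no column was left out. Chromosomes X and Y were left out, which left 438775 peaks on the 22 autosomes.

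Autosomal totals per library ran from 2391227 to 28564424 counts in DualCC and from 6569103 to 23862434 in noCC. Median counts per nucleus ran from 663 to 3660 in DualCC and from 1935 to 6793 in noCC. Wilson 95% intervals are given for shares of single libraries and cover counting error only.

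Gene positions came from the RefSeq annotation of GRCh38, with 19122 autosomal protein-coding genes. The annotation table gives no strand, so transcription start sites could not be told from gene ends. The planned promoter windows were therefore replaced by windows of 2 kb on either side of both ends of each gene, and 18022 genes had a peak there. Of the genes with such a peak, 45.7% shared a peak with a neighbour, and non-coding genes in the windows were not separated. Distal peaks lay over 2 kb from all ends of protein-coding genes and were given to the nearest end within 100 kb. For cell classes, counts were summed over the gene body and 2 kb beyond both ends.

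Counts were summed over nuclei per library. Marks were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 16 libraries with segment as a covariate, TMM factors and filterByExpr. Genes passed at an adjusted p under 0.05 and a difference of at least 2-fold. TMM assumes that most genes do not differ, which is uncertain between marks, so library totals alone served as an alternative. The DualCC and noCC tables of each library were compared with library as a block. Named genes had a mean of at least 20 CPM and the same direction within both segments; they are the 10 with the largest difference each way, or members of the gene lists. Genes at loci where people commonly differ in copy number or sequence were not named. The share of counts at gene ends was compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over the 6 tests.

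A set of 25 gene lists, fixed before the data were examined together with the tests, thresholds and most alternatives, was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as a check, at an estimated correlation. Cell classes came from the noCC table only. Peaks seen in at least 0.5% of nuclei (168149 peaks) went through TF-IDF and latent semantic indexing with 30 components, and the first, which followed depth (r = 0.93), was left out. Leiden clusters (leidenalg 0.10.2, igraph 0.11.9, 30 neighbours, resolution 0.6) were named from the marker lists. A name needed a mean log2 difference of at least 0.5 from the other clusters, a lead of 0.2 over the next list, at least 3 markers at that difference, at least 1 marker among the top 10 genes and at least 100 nuclei. DualCC counts of each class were then compared with those of the other named classes within libraries, for libraries with at least 20 nuclei in the class; markers passed at an adjusted p under 0.05 without a minimum difference. No doublet caller was run; the alternative without the top 5% of nuclei by counts covers part of this. Lumbar and thoracic libraries were compared without a test, as log2 ratios of mean CPM with a pseudocount of 1, and list medians were set beside 10000 random lists of matched mean.

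Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and DESeq2 1.42.0. The fits were tested on simulated data with 200 changed genes drawn from the real means and library sizes. For H3K27ac against H3K27me3 in DualCC, 100% of genes changed by a log2 of 1.5 and 100% of those changed by 3 passed, with 2 other genes among 17082. For H3K27ac against H3K4me1 these were 99% and 100%, with 1 other gene among 17074. For neurons against other classes, recovery at a log2 of 1.5 was 67% in H3K27ac libraries, 79% in H3K4me1 libraries and 35% in H3K27me3 libraries. At 3 it was 86%, 96% and 87%. These class simulations used gene-end sums and required a 2-fold difference. The class test itself used gene-body sums without a minimum difference, so its own recovery was not measured. Alternatives were DESeq2's Wald test, library totals, no low-count filter, windows of 500 bp, a distal limit of 50 kb, no segment term, a block of segment and replicate number, each segment alone, nuclei above the 25th percentile of counts, thinning to the lowest total, other cluster settings and leaving out each library. Windows at the presumed start only, leaving out both lumbar H3K27ac libraries that stood apart and merging near-identical libraries were chosen after seeing the data.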

Results

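The series profiled 1 histone mark and chromatin accessibility together in single nuclei of human spinal cord, and its title concerns enhancers and anatomically restricted cell states. H3K27ac marks active promoters and enhancers, H3K4me1 marks primed and active enhancers, and H3K27me3 marks genes repressed by Polycomb complexes. There were 4 lumbar and 3 thoracic H3K27ac libraries, 3 lumbar and 3 thoracic H3K4me1 libraries, and 2 lumbar and 1 thoracic H3K27me3 libraries. The DualCC table, read here as the antibody-directed fragments, held between 2391227 counts (thoracic H3K27ac replicate 2) and 28564424 counts (thoracic H3K27me3 replicate 1) per library. In lumbar libraries its totals were 4228904 to 7587360 counts for H3K27ac, 4170606 to 7963059 for H3K4me1 and 6659336 to 7374830 for H3K27me3. In thoracic libraries they were 2391227 to 10563120 counts for H3K27ac and 6525077 to 8062949 for H3K4me1. The noCC table, read here as accessibility, held 6569103 (lumbar H3K4me1 replicate 3) to 23862434 counts (thoracic H3K27me3 replicate 1). Libraries held 1083 to 6127 nuclei. A total of 6 pairs of libraries of the same group differed by little more than counting noise across genes (chi-square per degree of freedom 1.05 to 1.12), so these pairs carry less independent information than separate samples would.

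The share of DualCC counts at gene ends ordered the marks. It was 48.0% ± 3.03 (SD, n = 7) for H3K27ac, 40.2% ± 3.12 (SD, n = 6) for H3K4me1 and 29.1% ± 4.29 (SD, n = 3) for H3K27me3, the mark that also covers broad repressed domains away from genes. H3K27ac exceeded H3K27me3 by 18.9 percentage points (adjusted p = 0.0238) and H3K4me1 exceeded it by 11.1 points (adjusted p = 0.0238) in exact two-sided permutation tests. H3K27ac exceeded H3K4me1 by 7.74 points (adjusted p = 0.0175, exact two-sided permutation test). These tests, and those of noCC below, count each library as a separate sample. Some libraries of the same group were near-identical, among them both lumbar H3K27me3 libraries (chi-square per degree of freedom 1.05 in DualCC). The tests were not repeated with such libraries merged, so their p-values may be too small. The order also held within each segment: the H3K27ac excess over H3K27me3 was 18.4 points in lumbar and 21.2 points in thoracic libraries. In noCC the order was the other way, with 35.8% ± 4.23 (SD, n = 7) in H3K27ac, 41.9% ± 2.91 (SD, n = 6) in H3K4me1 and 43.9% ± 4.13 (SD, n = 3) in H3K27me3 libraries. The noCC difference of -6.06 points between H3K27ac and H3K4me1 passed (adjusted p = 0.0245, exact permutation test). Without lumbar H3K4me1 replicate 1 it was -5.52 points and without thoracic H3K4me1 replicate 3 it was -5.38 points, and in both cases it no longer passed. The difference of -8.07 points from H3K27me3 did not pass (adjusted p = 0.05, exact permutation test), nor did that of H3K4me1 from H3K27me3 (-2.01 points, adjusted p = 0.393, exact permutation test). In thoracic libraries H3K4me1 exceeded H3K27me3 by 4.01 points, so the place of these 2 marks in the noCC order did not hold within each segment. Without lumbar H3K27me3 replicate 1 or 2, the DualCC excesses over H3K27me3 were 20.05 or 20.2 points for H3K27ac and 12.3 or 12.4 points for H3K4me1, and did not pass. With all libraries the unadjusted p-values were already the smallest possible (0.00833 and 0.0119, exact permutation test). Fewer libraries raise that minimum, so the lost calls do not show a smaller difference. In single libraries the lowest DualCC share was 24.1% (Wilson 95% interval 24.1% to 24.2%) in thoracic H3K27me3 replicate 1, and the highest was 52.1% (52.0% to 52.1%) in lumbar H3K27ac replicate 1.

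**Figure D1:**
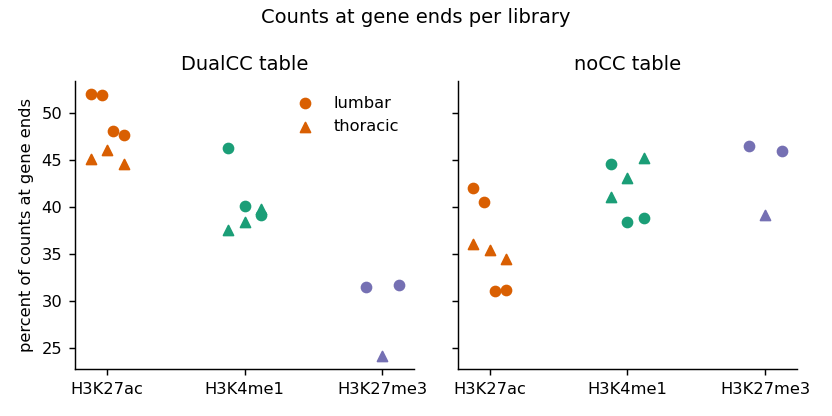
Percent of autosomal counts at gene ends (vertical axis) for each library, by mark, in the DualCC and noCC tables; circles are lumbar and triangles thoracic libraries. In DualCC the 3 H3K27me3 libraries lie between 24.1% and 31.7%, under all others.

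H3K27ac against H3K27me3 asks, in sums over all nuclei, which genes of the spinal cord are active and which are held under Polycomb repression. Developmental regulators were among the genes with the largest excess of H3K27me3 at gene ends. DMRT1 (chromosome 9, 841697 to 969090), a regulator of testis development, was lower in H3K27ac by a log2 difference of -5.43 ± 0.11 (SE), with 4.89 ± 0.60 CPM in H3K27ac (SD, n = 7) and 98.6 ± 26.1 in H3K27me3 libraries (SD, n = 3). The keratin-associated gene KRTAP10-12 was at -5.39 ± 0.12 (SE). FEZF2, a transcription factor of forebrain projection neurons, was at -5.20 ± 0.12 (SE), and MNX1 (chromosome 7, 157004854 to 157010663), which specifies motor neurons, at -5.10 ± 0.09 (SE). PAX7, a dorsal neural tube and muscle stem cell factor, was at -5.08 ± 0.12 (SE). H3K27ac was in excess at FRMD8 (chromosome 11, 65368026 to 65413525; 3.22 ± 0.12, SE). It was also in excess at DDIT4, a stress-induced inhibitor of mTOR signalling (2.87 ± 0.11, SE), and at SOX10, the oligodendrocyte lineage factor (2.47 ± 0.12, SE). QKI, an RNA-binding regulator of myelination, shared its window with LOC124901234 and was at 2.76 ± 0.16 (SE). Of 17185 genes, 8987 passed edgeR's quasi-likelihood test, 3692 higher in H3K27ac and 5295 higher in H3K27me3. On library totals without TMM, 13091 passed, 76.0% of them higher in H3K27ac instead of 41.1%, and the median log2 difference of all genes was 1.36 instead of 0.15. Directions below are therefore relative to that median.

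All 22 measured forebrain and midbrain factors were lower in H3K27ac (median -4.56), from LHX8 of basal forebrain neurons (-5.33) to TBR1 of cortical neurons (-2.98). So were all 38 factors of non-neural lineages (median -4.54; MYOG of skeletal muscle -1.49) and 37 of 40 spinal patterning factors (median -4.22). Among the latter NKX2-2, which remains active in oligodendrocyte lineage cells, was -0.48 and is among the 3 that did not reach 2-fold. With an estimated correlation camera's adjusted p was 0.0467 for the non-neural list, 0.0941 for the forebrain list and 0.104 for the spinal list. Only the first of these calls thus held, that is, passed with both correlations. At the preset correlation camera made 45 calls in all, and regroupings of the libraries gave a median of 34. Camera is therefore weak support for single lists. The regroupings were not run with the estimated correlation. All 12 HOX genes of paralog groups 10 to 13 were lower (median -4.21, HOXB13 -4.93), and camera's adjusted p was 0.124 with an estimated correlation. Of the 27 HOX genes of groups 1 to 9, 13 were lower and 14 were neither (median -0.89, which turns to 0.28 on library totals); adjusted p = 0.507 with an estimated correlation. Neuronal genes were lower for 10 of 11 members (median -3.52; the glycine transporter SLC6A5 -5.06; SNAP25 of synaptic vesicle fusion -0.41, not past 2-fold), and camera held (adjusted p = 0.0343 with an estimated correlation). Neurons were 4.27% of nuclei, so sums over all nuclei do not show the state of these genes in neurons. Against the other classes, neurons had 7 of 8 measured markers higher in H3K27ac and 4 of 12 lower in H3K27me3. All 5 cholinergic genes (median -4.95; adjusted p = 0.0598 with an estimated correlation) and 7 of 8 endothelial genes (median -2.88; adjusted p = 0.0467 with an estimated correlation) were lower. For every list in these comparisons the counts adjusted over the list alone were the same as those over all genes.

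Ubiquitous genes lay on the other side. Of 28 housekeeping genes 20 were higher in H3K27ac and 8 were neither (median 1.52, SDHA 0.06), and camera held at adjusted p = 0.0494 with an estimated correlation. For ribosomal proteins, 31 of 68 were higher (median 0.91, RPL12 1.81), and adjusted p = 0.0517 with an estimated correlation. For cholesterol synthesis, 6 of 16 were higher (median 0.87, IDI1 1.90; adjusted p = 0.0476 with an estimated correlation). Glial lists were mixed. Among oligodendrocyte genes 2 of 11 were higher, CNP of the myelin sheath at 2.60 and MBP at 1.01, and none was lower. The astrocyte list had 9 of 10 lower and SLC1A3, a glutamate transporter, higher at 1.61 (median -1.26; adjusted p = 0.133 with an estimated correlation). The precursor list had 6 of 10 lower, led by PDGFRA (-2.85); its median of -1.19 turns to 0.01 on library totals, and adjusted p = 0.124 with an estimated correlation. The microglia list had 5 of 10 lower and 2 higher, from ITGAM (-3.70) to AIF1 (1.59). Its median of -1.16 turns to 0.08 on library totals. Cell makeup also differed between marks. Microglia were 9.33% (lumbar) and 6.88% (thoracic) of nuclei in H3K27ac libraries, against 24.9% and 16.4% in H3K27me3 libraries. For oligodendrocytes these were 17.1% and 12.4% against 26.0% and 26.0%. Single lumbar H3K27ac libraries ranged widely, from 1.46% to 18.2% for microglia and from 6.47% to 29.5% for oligodendrocytes. The lumbar gap for oligodendrocytes therefore did not hold in every library. Astrocyte shares were closer (11.3% and 20.2% against 12.8% and 18.4%). How far this moved the glial lists was not tested. Among glial lineage factors 3 of 14 were higher and 3 lower, with SOX10 at the top and NFIB (-2.46) at the bottom; the median of -0.27 turns to 0.89 on library totals. Meningeal fibroblast genes (4 of 4 lower, adjusted p = 0.115 with an estimated correlation), genes of other tissues (14 of 17 lower, 0.0531) and axon guidance genes (16 of 21 lower, 0.124) lost their camera calls. The remaining lists did not pass camera: mural (4 of 7 lower), ependymal (3 of 7), Schwann cell (2 of 5), lymphocyte (4 of 6), reactive astrocyte (6 of 12 lower, 1 higher) and immediate early genes (5 of 13 higher, 1 lower).

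**Figure D2:**
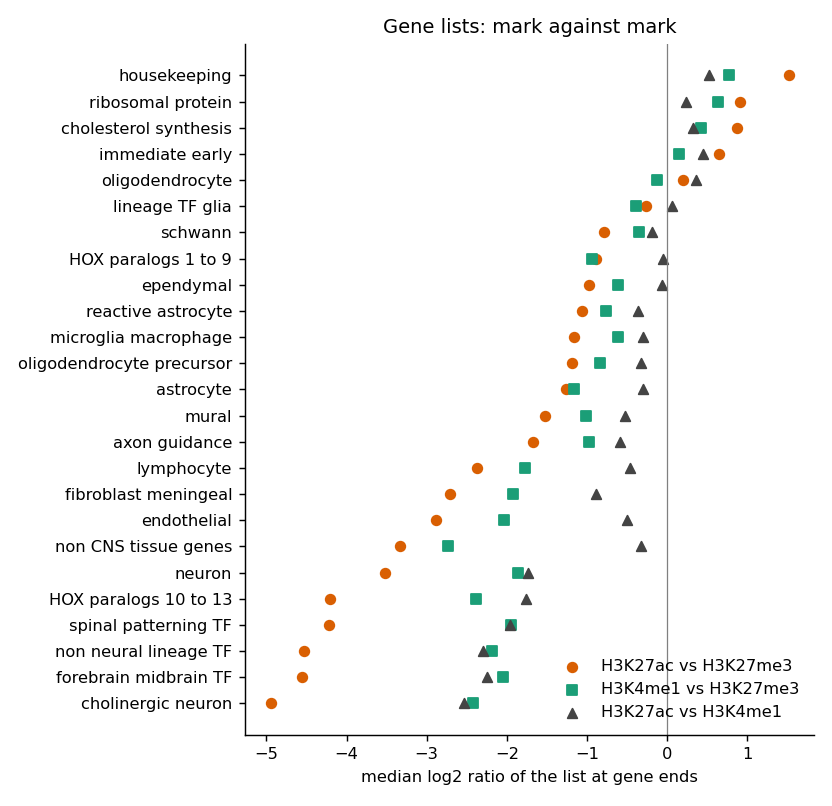
Median log2 ratio at gene ends (horizontal axis) of each gene list (vertical axis) in the DualCC table with TMM factors, for H3K27ac over H3K27me3 (circles), H3K4me1 over H3K27me3 (squares) and H3K27ac over H3K4me1 (triangles). The lists of forebrain (-4.56) and non-neural (-4.54) factors lie near the bottom and housekeeping genes (1.52) at the top; on library totals the precursor, microglia, ependymal, Schwann, reactive astrocyte, glial factor and HOX 1 to 9 medians of the first comparison turn positive, as do the oligodendrocyte, precursor, microglia, ependymal, Schwann, reactive astrocyte and glial factor medians of the second and the ependymal, Schwann and HOX 1 to 9 medians of the third.

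H3K4me1 against H3K27me3 asks the same of primed chromatin. FRMD8 (3.16 ± 0.13, SE) and SOX10 (2.35 ± 0.12, SE) were again higher, as was the histone demethylase gene KDM2B (2.52 ± 0.16, SE). ARHGEF2, a microtubule-associated exchange factor, shared its window with RXFP4 and was at 2.56 ± 0.12 (SE). Among the lower genes were the imprinted gene DLK1 (-4.03 ± 0.10, SE), with 10.3 ± 1.21 CPM in H3K4me1 (SD, n = 6) and 88.6 ± 10.8 in H3K27me3 libraries (SD, n = 3), and KRTAP10-12 (-4.39 ± 0.12, SE). The fibroblast growth factor gene FGF3 was at -3.93 ± 0.11 (SE). Of 17185 genes 6794 passed edgeR's quasi-likelihood test, 2297 higher in H3K4me1 and 4497 higher in H3K27me3. Library totals gave 10872, 78.9% of them higher instead of 33.8%, and a median of all genes of 1.00 instead of 0.04. The developmental lists were lower by smaller amounts than for H3K27ac: all 22 forebrain factors (median -2.05; adjusted p = 0.0952 with an estimated correlation), all 38 non-neural factors (-2.19; 0.0467) and 37 of 40 spinal factors (-1.95; 0.109). Of 28 housekeeping genes 12 were higher and none lower (0.77; adjusted p = 0.0496 with an estimated correlation). Oligodendrocyte genes had a median of -0.13, which turns to 0.86 on library totals, while camera's direction was up without passing; 2 of 11 were higher (CNP 2.08, MBP 1.24). The H3K27ac and H3K4me1 comparisons share the H3K27me3 libraries. They shared 2109 higher genes (493.5 expected if independent) and 4437 lower genes (1386 expected), with r = 0.957 across genes. In 5 simulations of unchanged groups the shared libraries alone gave r = 0.581, a covariance of 0.0145 against 2.32 observed, and 0 shared calls by edgeR. The 3 H3K27me3 libraries were not split into separate controls for the comparisons, since 1 set would hold a single library. Part of the overlap may therefore come from them.

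H3K27ac against H3K4me1 asks where active and primed chromatin part. Among the genes with more H3K27ac, BRD2, a reader of acetylated histones (chromosome 6, 32968594 to 32981505), was at 1.51 ± 0.07 (SE), with 129 ± 16.5 CPM in H3K27ac (SD, n = 7) and 36.8 ± 8.64 in H3K4me1 libraries (SD, n = 6). KMT2E, a chromatin regulator whose window is shared with SRPK2, was at 1.28 ± 0.09 (SE), and B2M of antigen presentation, shared with PATL2, at 1.20 ± 0.09 (SE). HNRNPA2B1 and CBX3 share 1 window at 1.21 ± 0.10 (SE). Nearly all genes with more H3K4me1 also had more H3K27me3 than H3K27ac. DMRT1 was at -3.28 ± 0.11 (SE), FEZF2 at -3.23 ± 0.12, the forebrain factor OTX2 at -3.04 ± 0.11, the GABA synthesis gene GAD2 (shared with MYO3A) at -2.88 ± 0.12 and SLC6A5 at -2.86 ± 0.11. For FEZF2 the CPM were 4.68 in H3K27ac, 38.2 in H3K4me1 and 81.9 in H3K27me3 libraries. In edgeR's quasi-likelihood test 1282 of 17185 genes passed, 58 with more H3K27ac and 1224 with more H3K4me1. Library totals gave 1214, with 31.4% instead of 4.52% higher in H3K27ac, and a median of all genes of 0.27 instead of 0.02. Of the 1224 genes, 1217 were also lower in H3K27ac than in H3K27me3 (377 expected if independent; r = 0.741 across genes). These comparisons share the H3K27ac libraries, which in 5 simulations of unchanged groups gave r = 0.427, a covariance of 0.00776 against 0.778 observed, and 0 shared calls by edgeR. All 22 forebrain factors were lower (median -2.24; adjusted p = 0.0467 with an estimated correlation), as were 32 of 38 non-neural factors (-2.30; 0.0343), 29 of 40 spinal factors (-1.96; 0.0598), 8 of 12 HOX genes of groups 10 to 13 (-1.76; 0.0897) and all 5 cholinergic genes (-2.54; 0.0343). Neuronal genes were lower for 8 of 11 (-1.73; 0.0343). No HOX gene of groups 1 to 9 reached 2-fold in edgeR's test, and their median of -0.05 turns to 0.21 on library totals.

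Distal peaks give the same comparison at candidate enhancers. Distal H3K27ac exceeded H3K4me1 near CDKN2C, a cell cycle inhibitor (1.27 ± 0.12, SE, n = 7 and 6), and near ZCCHC3 (1.18 ± 0.11, SE). It was lower near the patterning factors FEZF1 (-2.50 ± 0.15, SE), NKX3-2 (-2.24 ± 0.12, SE) and ISL1 of motor neurons (-2.17 ± 0.12, SE). A total of 365 of 15538 genes passed edgeR's test, 209 higher and 156 lower. On library totals 326 passed, 26.7% of them higher instead of 57.3%, so the split between directions depends on the scaling. Without thoracic H3K4me1 replicate 1, 318 passed, 144 higher and 174 lower. Of the 14336 genes measured in both regions, 82 were lower both at gene ends and distally (11.5 expected if independent). Of 44 genes higher at gene ends and 188 higher distally, 1 was shared (0.577 expected if independent), and r across genes was 0.264; both sums come from the same libraries. Against H3K27me3, 10186 genes passed for distal H3K27ac and 9569 for distal H3K4me1. The circadian factor TEF (4.63 ± 0.15, SE) had among the larger distal H3K27ac excesses. The distal H3K27me3 excess was large at SIM1, a hypothalamic factor (-3.88 ± 0.12, SE), the limb factor TBX3 (-3.85 ± 0.13, SE) and LHX5 of spinal interneurons (-3.80 ± 0.10, SE).

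In noCC, read here as accessibility, the same libraries would differ little if its counts did not depend on the antibody and the nuclei were alike. The nuclei were not alike. Unnamed nuclei were 51.5% (lumbar) and 43.3% (thoracic) in H3K27ac libraries, against 25.5% and 28.1% in H3K27me3 libraries. List medians of H3K27ac over H3K27me3 libraries had the opposite sign to DualCC. Forebrain factors were at 0.65 in noCC and -4.56 in DualCC, housekeeping genes at -0.38 and 1.52. Only the microglia, HOX 1 to 9 and glial factor medians kept their DualCC sign. Counts in noCC thus varied with the mark of the library, for a reason that was not tested. Against the H3K27me3 libraries, 552 of 17732 genes were higher and 2 lower in H3K27ac libraries, most at low levels: their median was 1.82 CPM against 23.8 for all genes tested. Those above 20 CPM included the growth factor gene FGF5 (1.13 ± 0.20, SE). The total of 554 was 241 on library totals, 161 higher and 80 lower. It was 0 in thoracic libraries alone, 49 without both lumbar H3K27ac libraries that stood apart, 67 with a replicate block and 77 with near-identical libraries merged, and 5 of 100 splits of the libraries gave as many, so these calls depend on few libraries. Leaving out 1 library moved it to 263 (lumbar H3K27ac replicate 3), 279 (lumbar H3K27ac replicate 4), 268 (lumbar H3K27me3 replicate 1), 279 (lumbar H3K27me3 replicate 2) or 990 (thoracic H3K27me3 replicate 1). Against H3K4me1 libraries 152 were higher and 2 lower, on library totals 38 and 27. PCBP1, an RNA-binding protein gene, and its neighbour ASPRV1 share a window and were the lower genes (-1.08 ± 0.09 and -1.02 ± 0.09, SE). The count of 154 was 263 without lumbar H3K27ac replicate 1 and 240 without lumbar H3K4me1 replicate 2. It was 66 without lumbar H3K27ac replicate 3, 64 without lumbar H3K27ac replicate 4 and 90 without thoracic H3K4me1 replicate 3. It was 6 in lumbar and 268 in thoracic libraries alone, 13 without both lumbar H3K27ac libraries that stood apart, 18 with near-identical libraries merged, 53 with a replicate block and 67 after thinning. Between H3K4me1 and H3K27me3 libraries edgeR called 0 genes, with 3916 at an unadjusted p under 0.05, and DESeq2 called 0. That count was 147 in thoracic libraries alone and 7 without thoracic H3K27me3 replicate 1, the highest of the fits without 1 library.

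DualCC against noCC within the same nuclei compares the antibody-directed counts with those read as accessibility. The noCC counts also varied with the mark, so the ratio does not fully separate them. In H3K27me3 libraries, DMRT1 was higher in DualCC by 3.89 ± 0.14 (SE), with 98.6 ± 26.1 CPM in DualCC and 12.6 ± 0.99 in noCC (SD, n = 3), and PDX1, a pancreatic factor, by 3.89 ± 0.16 (SE). HOXB13, which shares its window with PRAC1 and PRAC2, was higher by 4.04 ± 0.23 (SE). FRMD8 (-3.18 ± 0.16, SE) and DDIT4 (-3.06 ± 0.17, SE) were open but lacked H3K27me3. All 22 forebrain, all 38 non-neural and 37 of 40 spinal factors were higher in DualCC, and 21 of 28 housekeeping genes were lower. In H3K27ac libraries the phosphatase inhibitor gene PPP1R14A (1.41 ± 0.07, SE, n = 7), the oligodendrocyte protease gene KLK6 (1.30 ± 0.10, SE) and QKI (1.22 ± 0.06, SE) were higher. PENK, which encodes enkephalin (-2.31 ± 0.13, SE), and the potassium channel gene KCNS2 (-2.22 ± 0.12, SE) were lower in DualCC. So were GAD2 (-2.18 ± 0.17, SE) and the acetylcholine synthesis gene CHAT (-2.16 ± 0.11, SE, shared with SLC18A3). Their noCC levels in these libraries were 23.9, 29.4, 23.1 and 37.2 CPM. The median of all genes tested was 23.8 CPM over all libraries. DMRT1 fell as much (-2.12 ± 0.12, SE) at 16.5 CPM in noCC, so the lower ratio shows little H3K27ac and not openness. In H3K4me1 libraries NR2E1, a neural stem cell factor (1.67 ± 0.09, SE, n = 6), was higher, and BRD2 was lower (-1.60 ± 0.09, SE). The genes that passed edgeR's test numbered 9021 in H3K27me3 libraries (5244 higher, 3777 lower), 2367 in H3K27ac libraries (65 higher, 2302 lower) and 796 in H3K4me1 libraries (412 higher, 384 lower). Library totals gave 11923 (2675 higher, 9248 lower), 2560 (1260 higher, 1300 lower) and 840 (213 higher, 627 lower), and moved the median of all genes in H3K27me3 libraries from -0.11 to -1.08. Among the 17177 genes measured in both comparisons, 4835 were higher in DualCC of H3K27me3 libraries, and 4730 of them also had more H3K27me3 than H3K27ac (1490 expected if independent; r = 0.975 across genes); both comparisons use the DualCC counts of the same H3K27me3 libraries. In 5 simulations of unchanged groups those counts alone gave r = 0.581, a covariance of 0.0148 against 2.41 observed, and 0 shared calls by edgeR.

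Cell classes drawn from accessibility alone were oligodendrocytes (20.4% of nuclei, mean of 16 libraries), astrocytes (15.7%), microglia and macrophages (14.0%), oligodendrocyte precursors (8.77%) and neurons (4.27%), while 36.8% of nuclei stayed unnamed. At doubled cluster resolution no cluster met the naming rule for microglia and 60.2% stayed unnamed. A cluster of 2618 nuclei had 11 of 12 microglia markers at the required difference (mean log2 0.98) but none among its top 10 genes. Another of 3353 nuclei had a mean of 0.49, just under the 0.5 needed. The microglia results below therefore depend on the naming rule as well as on the cluster resolution. Precursors made up 12.8% ± 2.84 (SD, n = 7) of nuclei in thoracic and 5.68% ± 0.90 (SD, n = 9) in lumbar libraries, without overlap (8.41% to 16.3% against 4.19% to 6.64%). Neurons made up 5.05% ± 0.78 (SD, n = 9) of lumbar and 3.28% ± 0.44 (SD, n = 7) of thoracic nuclei. Neither difference was tested, since each segment came from 1 donor. Lumbar H3K27ac replicates 3 and 4 stood apart with 72.9% and 73.4% unnamed nuclei, against 29.4% and 30.4% in replicates 1 and 2.

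The antibody-directed counts followed cell identity. They played no part in defining the classes, but the same marker lists named the classes from noCC of the same nuclei. In H3K27ac libraries the water channel gene AQP4 was higher in astrocytes by 2.60 ± 0.17 (SE, n = 7) and RFX4 by 2.12 ± 0.09 (SE). APBB1IP was higher in microglia by 2.55 ± 0.19 (SE), the splicing factor gene RBFOX3 in neurons by 2.51 ± 0.07 (SE), and the myelin gene MAG in oligodendrocytes by 1.78 ± 0.10 (SE). PDGFRA, the growth factor receptor of precursors, was higher there by 2.36 ± 0.12 (SE). In H3K27me3 libraries the same identity genes were depleted in their own class: MOBP of myelin (-2.62 ± 0.25, SE, n = 3) and MAG (-2.17 ± 0.19, SE) in oligodendrocytes, DOCK8 (-1.92 ± 0.12, SE) in microglia and PTPRZ1 (-2.10 ± 0.30, SE) in precursors. PDGFRA in precursors had less H3K27me3 (-1.45 ± 0.17, SE) but no difference past the threshold in H3K4me1 (0.17 ± 0.10, SE, n = 6). At an adjusted p under 0.05, without a minimum difference, edgeR's test in H3K27ac libraries called 7 of 9 markers higher in astrocytes, 10 of 10 in microglia, 7 of 8 in neurons, 9 of 9 in oligodendrocytes and 10 of 10 in precursors, and none lower. In H3K4me1 libraries these were 8 of 10 (with PPP1R3G lower), 10 of 10, 2 of 12 (RBFOX3 2.59 and SYT1 0.99), 10 of 10 and 8 of 10. In H3K27me3 libraries none was higher by edgeR, and 8 of 10, 8 of 11, 4 of 12, 9 of 10 and 10 of 10 were lower. The astrocyte count was 5 of 10 without thoracic H3K27me3 replicate 1 (median -0.72 instead of -1.14), and the microglia count 5 of 9 with gene-end sums. The neuron count was 2 of 12 without lumbar H3K27me3 replicate 2 and 10 of 12 on library totals. With gene-end sums the H3K27ac counts were 5 of 5 in microglia and 4 of 5 in neurons. Markers of other classes also moved: in H3K4me1 libraries 10 of 43 were higher in oligodendrocytes (median -0.33), and in H3K27me3 libraries 20 of 42 were also lower in microglia (median -0.26 beside -1.30 for its own markers). In neurons the medians of their own and of other markers were 0.12 and -0.21 in H3K4me1 libraries and -0.63 and 0.62 in H3K27me3 libraries. The H3K4me1 median of neuronal markers has no settled direction, since it turns to -0.53 with gene-end sums, -0.063 without the top 5% of nuclei and -0.0082 on library totals. Adjusted over the list alone, 5 of the 12 neuronal markers were lower in H3K27me3, and all other counts were unchanged.

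**Figure D3:**
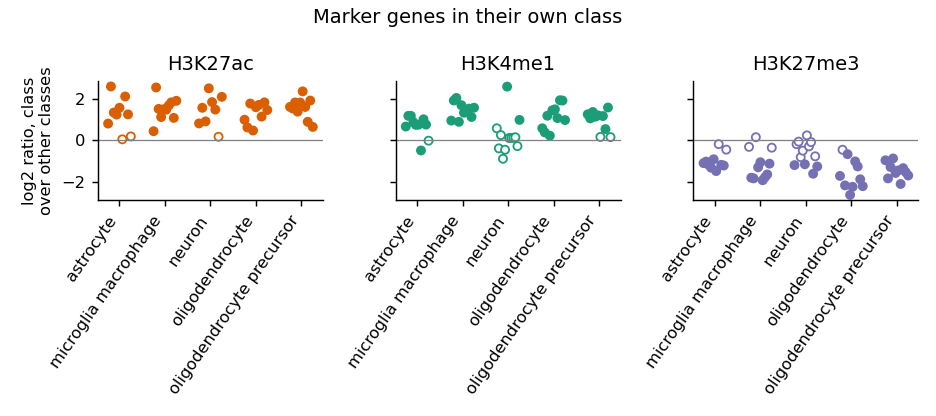
Log2 ratio of DualCC counts in a class over the other named classes (vertical axis) for each marker of that class (points), in H3K27ac, H3K4me1 and H3K27me3 libraries; filled points passed at an adjusted p under 0.05. The H3K27ac panel lies above 0 (AQP4 2.60), and most H3K27me3 points are negative (MOBP -2.62).

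Lumbar against thoracic cord concerns positional identity, which HOX genes encode along the body axis. No test was made, since with 1 donor per segment a difference between segments cannot be told from one between donors. HOXD10 (chromosome 2, 176116778 to 176119937), a lumbar motor neuron regulator, had 29.4 ± 1.60 CPM of H3K27ac in lumbar (SD, n = 4) and 18.8 ± 0.788 in thoracic libraries (SD, n = 3), a log2 ratio of 0.62. HOXC10 went the other way, with 41.4 ± 2.38 CPM in lumbar and 51.8 ± 3.75 in thoracic libraries (SD, n = 4 and 3; ratio -0.32). HOXD9 had a ratio of 0.69. In the other direction HOXB4 had a ratio of -0.70 and HOXC9, which specifies thoracic motor columns, of -0.38. At HOXC10, HOXB4 and HOXC9 all thoracic libraries lay above all lumbar libraries. H3K27me3 was higher in lumbar libraries at all 27 HOX genes of groups 1 to 9 (median 1.20; random lists 0.25 to 0.55) and at all 12 of groups 10 to 13 (median 0.81). Other lists shared this direction: all 40 spinal patterning factors (median 0.75), all 22 forebrain factors (0.63), 35 of 38 non-neural factors (0.60) and 13 of 14 glial factors (0.80), beside a median of 0.35 over all genes. HOXC9 had 100.2 ± 1.54 CPM in lumbar (SD, n = 2) and 37.0 in the single thoracic library. With TMM factors the median of groups 1 to 9 was 0.73. For H3K27ac the median of groups 1 to 9 was -0.20 (random lists 0.07 to 0.25), which turns to 0.033 in oligodendrocyte nuclei alone. Other lists were below their random ranges too: precursor (-0.25), astrocyte (-0.15), endothelial (-0.22) and axon guidance genes (-0.19). This shift was thus not particular to HOX genes. For H3K4me1 the HOX median was 0.04, which turns to -0.11 with TMM factors. Accessibility of these genes had a median of -0.17 over all libraries, which turns to 0.34 in the H3K27me3 libraries alone. Outside the HOX clusters, 3 genes met the naming rule with more accessibility in lumbar libraries: NNMT (0.45), which methylates nicotinamide, and the neighbours ADCY4 (0.30) and RIPK3 (0.29). The 3 with more in thoracic libraries were BMP7, a dorsal patterning signal (-0.49), STX8 (-0.40) and FXYD6 (-0.19).

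**Figure D4:**
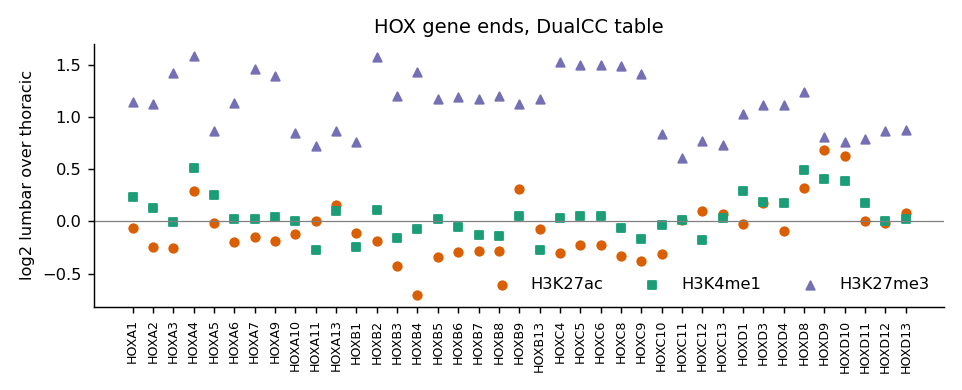
Log2 ratio of lumbar over thoracic CPM in the DualCC table (vertical axis) at the ends of each HOX gene, for H3K27ac (circles), H3K4me1 (squares) and H3K27me3 (triangles). All H3K27me3 points lie above 0 (HOXB4 1.43), and HOXD9 (0.69) and HOXD10 (0.62) have the largest H3K27ac ratios among the genes named here.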

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

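The comparisons between segments in this part, and the tests of HOX genes other than the one on lists matched for enrichment, were chosen after the results were seen. The thoracic segment has 1 H3K27me3 library, so edgeR's tests of whether a ratio to H3K27me3 differs between segments have no spread of their own for it, and an offset of that library alone could give their calls. They are listed here as differences of that library and were not read as differences between segments. HOXB4 is an anterior HOX gene of the neck and hindbrain. It had 20.6 CPM of H3K27ac and 62.0 of H3K27me3 in lumbar libraries, and 34.2 and 22.3 in thoracic libraries, so its log2 ratio of H3K27ac to H3K27me3 was lower in lumbar libraries (-1.93 in edgeR's fit). That ratio was also lower for HOXC9 (-1.48) and the neural stem cell factor SOX2 (-1.42), and higher for SFTPB, a surfactant gene (1.73). In DualCC, 385 genes were called for H3K27ac against H3K27me3, 286 with a higher and 99 with a lower ratio in lumbar libraries, among them 18 of 27 HOX genes of groups 1 to 9, all lower. For H3K4me1 against H3K27me3 these were 516 genes, 461 higher and 55 lower, with 12 of 27 HOX genes lower; the myeloid factor gene SPI1 (1.33) shares its window with MYBPC3, and the glial factor SOX9 was at -1.36. In noCC, read here as accessibility, the same test called 993 genes for H3K4me1 against H3K27me3, and 0 for H3K27ac against H3K27me3 by edgeR (2920 at an unadjusted p under 0.05). Counts in noCC also varied with the mark, so its calls cannot serve as a control free of the mark. For H3K27ac against H3K4me1, which does not involve that library, 35 genes were called in DualCC, 3 higher and 32 lower in lumbar libraries, and 0 in noCC by edgeR (1865 at an unadjusted p under 0.05). Segment and donor cannot be separated in any of these.

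The higher H3K27me3 at HOX genes of groups 1 to 9 in lumbar libraries (median 1.20, 27 of 27 genes) was weighed against weaker enrichment of the thoracic library. Random lists matched on the ratio of H3K27me3 to accessibility gave medians of 0.01 to 0.42, and the HOX median lay at percentile 100. This does not decide the question. The median log2 ratio of H3K27me3 to accessibility was 0.14 for the HOX genes. The matched lists may therefore carry too little H3K27me3 to show weaker enrichment. Neighbouring HOX genes also share peaks, and random lists do not copy that. Weaker enrichment stays open, since the spinal patterning (0.75), forebrain (0.63) and glial factors (0.80) were also higher in lumbar libraries, beside 0.35 for all genes. A difference in cell makeup as the whole cause was argued against by oligodendrocyte nuclei alone. There the HOX median exceeded that of all genes by 0.65 (quartiles 0.53 to 0.82), beside 0.85 in all nuclei. A positional difference in Polycomb repression along the cord may remain. So may a difference between donors, and weaker enrichment or another fault of the single thoracic library.

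Among the 4 lumbar H3K27ac libraries, replicate 2 was flagged for its DualCC counts (4228904, the lowest) and its share of neurons (6.002%, the highest). The gap to the next library was 0.834 and 0.866 of the range, where 0.829 is the limit for 4 libraries. These are 2 of 13 tests, of which chance gives about 1 in 20. Replicate 2 also held the fewest nuclei, 1083 beside 1851 to 2363 in the others, on which its neuron share rests. Its median of 1971 DualCC counts per nucleus lay within the 1809 to 2762 of the others, so its low total goes with few nuclei.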

How the results depend on the processing

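Windows at the presumed start, leaving out both lumbar H3K27ac libraries that stood apart, and merging near-identical libraries were chosen after seeing the data. All alternatives written beforehand were run, with windows at gene ends in place of start sites. Of 518 values that answer a comparison, 450 stayed within the limits set, 54 moved, 8 weakened, 6 strengthened and none was labelled reversed. Among those that moved, 4 values without a passing test changed sign: H3K4me1 less H3K27me3 in the noCC share and 3 of the HOX medians, all given below. Of 12038 values of single genes and lists, 11762 were the same, 175 weakened, 76 strengthened, 23 moved and 2 called genes lost their call with a change of sign: LOC102724560 in distal peaks (-0.39 with a 50 kb limit) and CX3CR1 of microglia in H3K4me1 (-0.014 with gene-end sums), neither past its threshold. In all, 119 of the 12038 values had another sign than in the original fit; all but these 2 were of genes not called there. The DualCC counts ranged over settings from 8106 to 13091 for H3K27ac against H3K27me3, 1214 to 1557 for H3K27ac against H3K4me1 and 300 to 531 for distal peaks. For the changes below the cause was not tested, except where fewer libraries or counts were used.

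On library totals, H3K4me1 against H3K27me3 in DualCC gave 10872 genes (6794 with TMM), noCC gave 241 (554) for H3K27ac against H3K27me3 and 65 (154) for H3K27ac against H3K4me1, and 1 class marker was higher in H3K27me3 (0 with TMM by edgeR, 0 by DESeq2). With segment and number as a replicate block, noCC gave 67 and 53; the numbers did not pair the samples, since 2 of 10 same-number pairs correlated above 0.1 in each table. Thinning gave 347, 67 and, for H3K4me1 against H3K27me3 in noCC (0 otherwise), 2. For that comparison no low-count filter gave 1, windows of 500 bp 2, lumbar libraries alone 2, thoracic libraries alone 147 and the presumed start 2. Thoracic libraries alone gave 0 for H3K27ac against H3K27me3 and 268 for H3K27ac against H3K4me1, and lumbar libraries alone gave 6 for the latter. Without both lumbar libraries that stood apart noCC gave 49, 3 and 13, and merging gave 77 and 18. Leaving out 1 library gave 263 to 990, 0 to 7 and 64 to 263. DualCC against noCC gave 1520 (2367) in H3K27ac libraries after thinning and 1323 (796) in H3K4me1 libraries without a filter. With an estimated correlation 15 list calls passed camera (45 with the preset).

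For the share at gene ends in noCC, H3K27ac less H3K27me3 was -8.19 points with 500 bp, -8.04 in nuclei above the 25th percentile and -8.03 at the presumed start, all 3 now past the threshold, -3.81 in thoracic libraries and -10.5 to -6.74 without 1 library. H3K4me1 less H3K27me3 was 4.01 in thoracic libraries. H3K27ac less H3K4me1 was -4.79 as a mean of single nuclei, -4.17 without both libraries that stood apart and -7.10 to -5.26 without 1 library. In DualCC, leaving out 1 library gave 16.4 to 20.2 for H3K27ac less H3K27me3 and 8.67 to 12.4 for H3K4me1 less H3K27me3.

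The HOX 1 to 9 median, lumbar over thoracic, was 0.34 in noCC of H3K27me3 libraries and 0.033 for H3K27ac in oligodendrocyte nuclei. For H3K4me1 it was -0.11 with TMM, 0.23 in oligodendrocyte nuclei and 0.19 with classes weighted equally; for H3K27me3 these were 0.73, 0.97 and 1.15. At doubled cluster resolution no cluster was named microglia (0.0%) and 60.2% of nuclei were unnamed. The lowest totals, 2391227 counts in DualCC and 6569103 in noCC, limit calls at genes with few counts.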

Other observations

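The tests in this part were chosen after the results were seen. Several neuronal and developmental genes had more H3K4me1 than H3K27ac. At SLC6A5, the glycine transporter of inhibitory neurons, H3K27ac was at 3.82 ± 0.50 CPM (SD, n = 7) and H3K4me1 at 22.5 ± 0.842 (SD, n = 6). At OTX2, a forebrain and midbrain factor, these were 4.25 ± 0.761 and 30.3 ± 2.60. The motor neuron gene MNX1 had 13.6 CPM of H3K27ac, 70.2 of H3K4me1 and 204 of H3K27me3.

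H3K4me1 above H3K27ac at gene ends that carry H3K27me3 was weighed against H3K27me3 fragments mixed into the H3K4me1 libraries. Mixing would bring distal and gene-end excess alike. Over all 5295 genes with more H3K27me3 than H3K27ac, the H3K4me1 excess over H3K27ac was 8.96% of the H3K27me3 excess distally and 20.8% at gene ends, a ratio of 0.431 (0.397 to 0.465). Among the genes of the pattern, picked in 1 segment and measured in the other, the ratio was 0.0761 (0.0623 to 0.0955, picked in lumbar libraries) or 0.446 (0.414 to 0.483, picked in thoracic libraries). These intervals resample genes, some of which share peaks. Those for genes picked in lumbar and in thoracic libraries exclude each other, so they miss the spread between libraries. The ratios argued against mixing as the whole cause only across genes. How much of the gene-end excess mixing could account for stays open. Shallower H3K27ac libraries were argued against by thinning, which gave 1321 genes in place of 1282. Bivalent marking of silent developmental genes, or nuclei of different states side by side, may remain and was not tested.

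Higher noCC counts in H3K27ac than in H3K27me3 libraries were weighed against nuclei outside the named classes and against depth. The 552 genes had a median log2 difference of 1.19 (quartiles 1.08 to 1.35). In nuclei of the named classes it was 0.87 (0.72 to 1.06, 351 genes measured), and 109 genes still passed, since most fell below 2-fold. Thinned to the lowest total it was 1.13 (0.99 to 1.34, 415 genes), and 249 still passed. A difference between libraries or between antibodies in how fragments were divided may remain, and no biological explanation was tested.

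Other splits of the libraries into groups of the same sizes tell whether chance can be excluded, if the libraries are separate samples, which 6 near-identical pairs put in doubt. It can for H3K27ac against H3K27me3 in DualCC (8987 genes; highest other split 0; 1 of 100 splits as large), H3K4me1 against H3K27me3 (6794; 2933; 1 of 84) and H3K27ac against H3K4me1 (1282; 774; 1 of 100). It can also for noCC H3K27ac against H3K4me1 (154; 56; 1 of 100) and distal peaks (365; 205; 1 of 100). With near-identical libraries merged these 3 comparisons of H3K27ac with H3K4me1 gave 1300, 18 and 397 genes, against 0 in the highest other split (1 of 35 each). The splits of the other results were not repeated on merged libraries, where most would be too few. For DualCC against noCC the splits swap the tables within some libraries, which cancels any steady difference. They therefore decide nothing in H3K27ac (2367, 1232, 1 of 64) and H3K4me1 libraries (796, 0, 1 of 32). For class markers the splits decide nothing in H3K27ac (43, 36, 1 of 64) and H3K4me1 libraries (38, 8, 1 of 32). They swap a class with the other nuclei within some libraries, which cancels any steady difference. The same marker lists also named the classes. Chance cannot be excluded for noCC H3K27ac against H3K27me3 (554, 1067, 5 of 100), where the higher split points to a structure among the libraries. Nor can it for the gene lists (45, 53, 18 of 100), where the other splits gave a median of 34. For noCC H3K4me1 against H3K27me3 the splits decide nothing. With 0 genes called by edgeR and by DESeq2, every split is as large (84 of 84, highest other split 18). In edgeR's test 3916 genes there had an unadjusted p under 0.05. In H3K27me3 libraries the 4 splits are too few for DualCC against noCC (9021; 0; 1 of 4) and for class markers (39; 0; 1 of 4).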
